A study of Mus musculus with 23 samples.

How the data were processed

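Chromatin accessibility was measured by ATAC-seq, which marks open DNA by the insertion of sequencing adapters, in 23 libraries of mouse intestinal epithelium. Per the labels, the libraries form 8 groups made from 3 ages and from duodenum or colon. The groups are juvenile duodenum, adult villus, adult crypt, geriatric villus, geriatric crypt, juvenile colon, adult colon and geriatric proximal colon. Each group has 3 libraries except geriatric proximal colon, which has 2, numbered 1 and 3, because the submitters set aside a library with poor DNA per the series description. Per the labels' protocols, each juvenile colon library pooled 6 animals and each adult colon or geriatric proximal colon library pooled 2. Group and replicate were taken from the sample titles alone.

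The deposited files are of 2 kinds. For each library there is a table of peaks, called by the authors on that library alone with MACS2 2.1.0.20150731 and without a control library, per the file headers. Per the file headers, the effective genome size was 1.87e+09, 1 read was kept per position, the local background was taken over 10 kb and the q cutoff was 0.05. The extension of each read was set per library and ranged from 68 to 210 bp per the file headers. Per the file headers, each peak carries a pileup signal, which is the number of extended reads stacked at its summit without scaling to depth. Each peak also carries the −log10 p-value and −log10 q-value of the authors' caller against the local background of the same library. The fold enrichment deposited for each peak is the ratio of pileup to that background. These per-peak values are the authors' own and were used here only to rank or filter peaks within a library. The submitters' processing notes name the mm9 genome build, cutadapt 1.9.1, Bowtie2, SAMtools 0.1.19, deepTools, bedtools 2.17.0 and Picard 2.18.27 without saying what each was used for. Adapter removal settings, alignment settings and any shift of reads for the transposase beyond the headers are not given in the sources used here.

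The other files are the 28 lists of regions deposited by the authors for 14 comparisons between groups, 1 list per direction, with a chromosome, a start and an end per region and no other value. The submitters' processing notes name DiffBind, a package for differential analysis of peak sets. The model, the normalization and the threshold behind the lists are not given in the sources used here. The lists were made from the same libraries that are compared here, so they are not independent evidence of direction in those groups.

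Peaks of the 23 libraries were merged into a catalogue of 149024 regions, of which 85469 held a peak in at least 2 libraries and were used. An overlap of at least 1 bp counted as shared. Because the lists held between 11355 and 60519 peaks, libraries were compared after each list had been reduced to its strongest peaks by −log10 p, to the size of the shortest list in the comparison. Full lists are named where they were used. A region of the catalogue was called exclusive to a group when every library of that group and no library of the other group had a peak there. Exclusive regions were also counted after every other division of the same libraries into groups of the same sizes, 10 divisions in each comparison. The similarity of 2 libraries was the Jaccard index, the number of catalogue regions called in both over the number called in either.

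For each of the authors' deposited lists, the share of its regions with a peak was taken in every library. Shares were compared between the 2 groups with a two-sided exact permutation test over libraries. That test cannot give a p under 0.1 with 3 against 3 or 3 against 2 libraries, so no such comparison can pass 0.05. Duodenum and colon labels were permuted 100000 times over the 23 libraries for the test of similarity. Lists of different comparisons were compared over catalogue regions with two-sided Fisher's exact tests, only between comparisons that share no library. Whether they share animals is not given in the sources used here, and the series description counts fewer mice than libraries. There were 17 pairs of comparisons, with 68 tests of overlap and 17 of direction, each family adjusted by the Benjamini-Hochberg method. The background of an overlap was the regions called in at least 2 libraries of both comparisons. Neighbouring regions are not independent replicates, so these Fisher tests describe the lists and not animals. The series description calls the replicates biological. The permutation p-values measure the spread between these libraries, which may be technical.

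Groups, comparisons, tests and most alternatives were fixed before the data were examined. The rule for naming regions was fixed then too. Per comparison and direction, the regions with a peak in the most libraries of the higher group and the fewest of the other could be named, up to 10, ties going to the wider region and then by position. Regions named outside this rule are said to have been chosen after their values were seen. The alternatives were full lists, peaks with −log10 q of at least 5, ranking by fold enrichment, the strongest 5000 peaks, catalogue regions called in at least 1 library, a peak covering at least 50% of one of the authors' or named regions, a reciprocal overlap of 50%, the whole catalogue as background, leaving out each library and pairing by replicate number. A further 4 alternatives were added after seeing the data. They were a peak covering at least 50% of the catalogue region for exclusive counts, autosomes alone for exclusive regions, autosomes alone for overlaps, and labels permuted over whole groups.

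Depth was read from the file headers and ranged from 14.4 to 47.9 M reads kept per library. A region without a peak in a library is one that did not pass the caller's threshold at that depth, not one shown to be closed. Gene names, distances to promoters, sequence motifs and the gene lists fixed for this tissue were not analysed here, because no mm9 annotation or sequence was used and the positions in the gene table at hand are of another build. Regions are therefore named by mm9 position, counted from 1.

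The analysis ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap steps were tested on simulated data made from adult villus and adult crypt, with 70777 regions and 400 planted differences. In the draw, 289 planted regions separated the groups and all 289 were found. Each simulated peak lay inside its own catalogue region and no list was cut, so this checks the code and not the rules on real peaks. The exclusive count was 1193 in the simulated division and at most 960 in the others. Of 1000 pairs of random lists, 4.5% gave a Fisher p under 0.05. Their regions were drawn independently, unlike neighbouring regions of the real lists, so this share does not show how the tests behave on those.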

Results

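Open chromatin was mapped in the epithelium of the mouse duodenum, the part of the small intestine next to the stomach, and of the colon at 3 ages. Juvenile mice were 12 days old for duodenum and 15 days old for colon, adult mice 90 days and geriatric mice 21 months. Juvenile duodenal epithelium was taken whole. Adult and geriatric duodenum was divided into villi, the projections that carry differentiated absorptive cells, and crypts, the pits that hold dividing cells. Colon has crypts but no villi. The geriatric colon samples were of proximal colon, the part next to the small intestine, and the labels of juvenile and adult colon name no part. The 8 groups held 3 libraries each, except geriatric proximal colon with 2. Between 32.7 and 95.7 M reads per library entered peak calling, and 14.4 to 40.5 M were kept in the 15 duodenum libraries and 20.5 to 47.9 M in the 8 colon libraries.

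Duodenum libraries had 46111 ± 7841 peaks (SD, n = 15) and colon libraries 21301 ± 6686 (SD, n = 8). Juvenile duodenum had 49022 ± 3572 peaks, adult villus 47867 ± 4209, adult crypt 48260.3 ± 11696, geriatric villus 39121 ± 3672 and geriatric crypt 46283 ± 12331 (SD, n = 3 each). Juvenile colon had 19971 ± 2472 peaks and adult colon 27371 ± 5816 (SD, n = 3 each), and the 2 geriatric proximal colon libraries had 17026 and 11355. Colon libraries kept more reads than duodenum libraries, 32.7 ± 9.07 M (SD, n = 8) against 23.3 ± 6.88 M (SD, n = 15), so the shorter colon lists did not come with lower depth. Kept reads did not track peak number within duodenum (Pearson r = −0.275, permutation p = 0.323, and Spearman rho = −0.146, permutation p = 0.598, n = 15). The same held within colon (Pearson r = 0.0220, exact permutation p = 0.960, and Spearman rho = 0.143, exact permutation p = 0.752, n = 8). Without the 2 libraries farthest from the median depth, r was −0.0704 in duodenum and 0.0919 in colon. The share of repeated reads did not track peak number in duodenum either (r = −0.0191, permutation p = 0.946, rho = −0.0233, permutation p = 0.937, r = 0.246 without the 2 farthest). In colon the values were r = −0.0626 (exact permutation p = 0.877), rho = −0.192 (exact permutation p = 0.648) and r = −0.0197 without the 2 farthest. Over these 4 relations the adjusted p was 0.960 for every r and 0.937 for every rho. All comparisons between libraries used lists of equal length unless stated.

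Libraries of the same tissue were more alike on average, but crypt libraries were no closer to villus than to juvenile or adult colon. With each list at its 11355 strongest peaks, the mean Jaccard index was 0.488 between libraries of the same tissue and 0.396 between a duodenum and a colon library (permutation p = 1e-05, the smallest that 100000 permutations can give). With whole groups moved together, 2 of the 56 ways to choose the groups gave as large a difference (exact permutation p = 0.0357). The larger of them, 0.0967 against 0.0917, set juvenile duodenum and both villus groups against crypts and colons. Adult crypt had an index of 0.415 ± 0.0248 with adult villus, 0.447 ± 0.00834 with juvenile colon and 0.432 ± 0.0106 with adult colon. Geriatric crypt had 0.416 ± 0.0148 with geriatric villus, 0.444 ± 0.0237 with juvenile colon and 0.427 ± 0.0184 with adult colon (SD of 9 pairs each). With geriatric proximal colon the values were lower, 0.391 for adult and 0.400 for geriatric crypt. Adult colon libraries were the most alike, with a mean index of 0.770 ± 0.0194 (SD of 3 pairs of libraries), followed by juvenile colon at 0.704 ± 0.00739 and juvenile duodenum at 0.634 ± 0.00269. Adult villus and geriatric villus were as similar to each other (0.547 ± 0.0379, 9 pairs) as adult villus libraries were among themselves (0.547 ± 0.0420, 3 pairs). Adult and geriatric crypt were likewise at 0.574 ± 0.0115 across ages against 0.579 ± 0.00717 within adult crypt. Geriatric proximal colon had an index of 0.424 ± 0.0243 with adult colon and 0.462 ± 0.0257 with juvenile colon (6 pairs each), close to the 0.467 of its own 2 libraries.

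**Figure D1:**
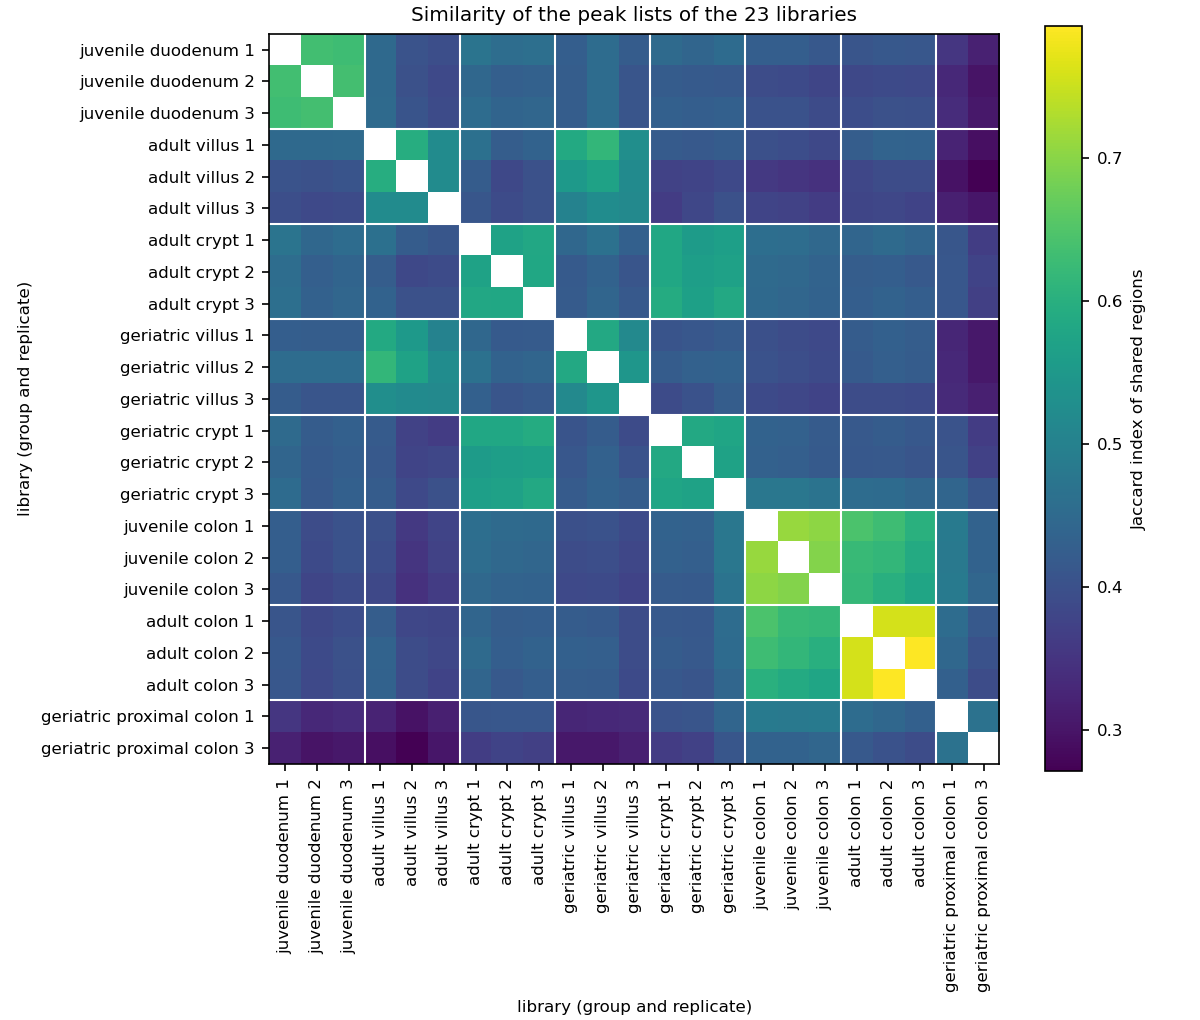
Jaccard index of catalogue regions (colour, no unit) for every pair of the 23 libraries, each reduced to its 11355 strongest peaks; white lines part the 8 groups. Adult colon is the most uniform group (mean 0.770), and villus and crypt of adult and geriatric mice each form a block across age.

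Crypt libraries lay closer to colon than villus libraries did. The mean index with juvenile colon was 0.447 ± 0.00635 for adult crypt and 0.372 ± 0.0206 for adult villus (SD, n = 3 each, exact permutation p = 0.1). With geriatric proximal colon it was 0.400 ± 0.0226 for geriatric crypt and 0.320 ± 0.00512 for geriatric villus (exact permutation p = 0.1). With adult colon the values were 0.432 ± 0.0112 for crypt and 0.400 ± 0.0283 for villus, which overlapped more (exact permutation p = 0.3). Juvenile duodenum had an index of 0.448 ± 0.00841 with adult crypt and 0.415 ± 0.0305 with adult villus (SD, n = 3 each, exact permutation p = 0.3). It was about equally close to geriatric crypt (0.433 ± 0.00316) and geriatric villus (0.431 ± 0.0221, exact permutation p = 0.9).

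The authors' deposited lists give, for 14 pairs of groups, the regions more accessible in each member of the pair. They were long for every comparison of region, compartment or juvenile against later age and short for adult against geriatric duodenum, where the authors' deposited lists hold 101 regions for villus and 117 for crypt. In each of the 28 lists the listed regions were called more often in libraries of the group named as higher. The two-sided exact permutation test gave p = 0.1 for each list, the smallest p that 3 against 3 or 3 against 2 libraries allow. The lists were chosen on these same libraries, so these shares describe the lists and are not independent evidence of their direction.

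**Figure D2:**
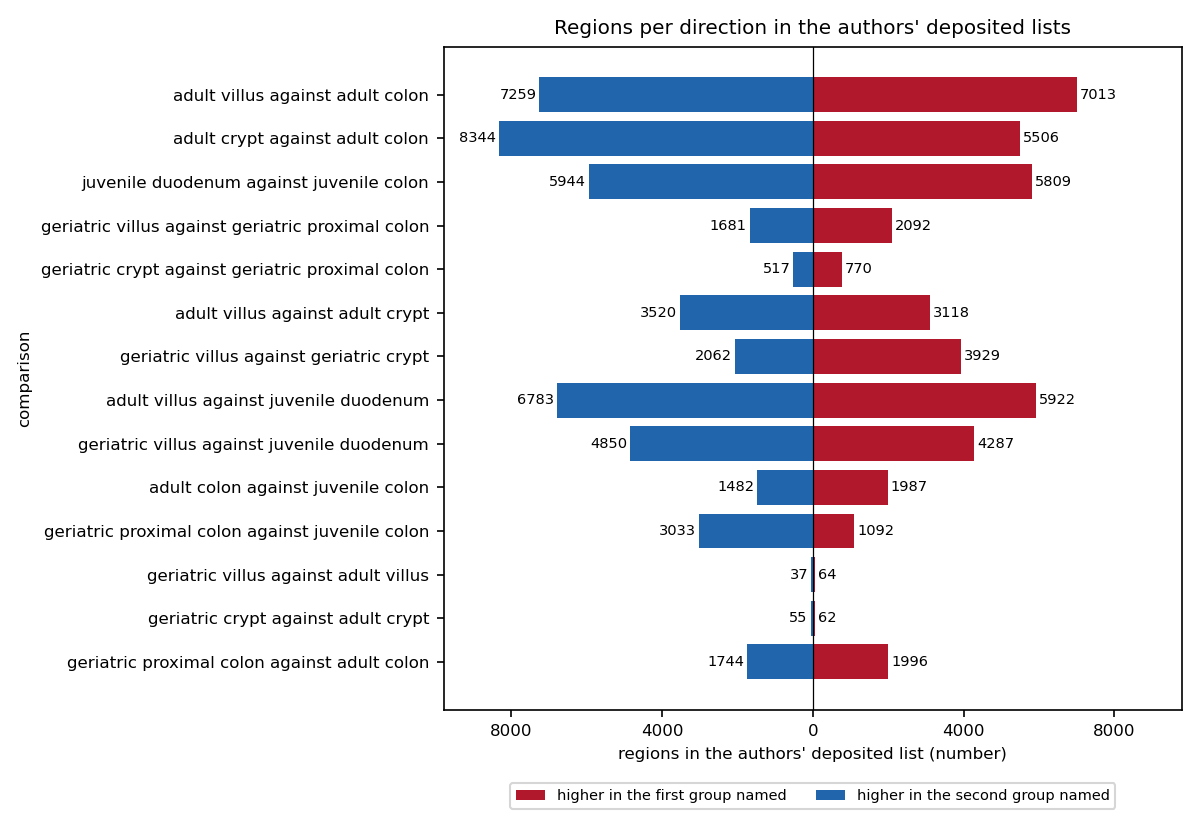
Number of regions in the authors' deposited lists for each of the 14 comparisons; bars to the right count regions higher in the group named before "against" and bars to the left those higher in the other. Lists for adult against geriatric villus and crypt hold between 37 and 64 regions.

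Adult villus and adult colon were compared to find regional differences in the mature epithelium. The authors' deposited lists hold 7013 regions higher in villus and 7259 higher in colon. Few of the villus regions had a peak in colon: 55.8% ± 4.80 of them had a peak in villus libraries and 1.95% ± 0.310 in colon libraries (SD, n = 3 each). The colon regions were graded, with a peak at 85.9% ± 1.75 in colon and still at 45.6% ± 2.32 in villus (SD, n = 3 each). With full lists, 2636 of the colon regions (36.3%) and 1 of the villus regions had a peak in all 23 libraries. The normalization behind the lists is not given, so this contrast may rest on a difference of scale, taken up under other observations. The region that leads the villus direction lies on chromosome 8 at 99392030 to 99393328 (mm9). It had a peak in all 15 duodenum libraries and in 0 of the 8 colon libraries, as did chromosome 1 at 90184077 to 90185197. Among the leading colon regions, that on chromosome 16 at 21381503 to 21382741 had a peak in the 3 adult colon libraries, in none of the other 5 colon libraries and in 4 duodenum libraries with full lists. Independently of the authors' lists, 3114 catalogue regions were exclusive to adult villus and 2973 to adult colon. Their total of 6087 compares with at most 210 in the other divisions of the 6 libraries, and it rose to 9289 without adult colon library 1, whose short list sets the length for all.

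Adult crypt and adult colon differed as widely. The authors' deposited lists hold 5506 regions higher in crypt and 8344 higher in colon. Crypt regions had a peak at 55.9% ± 0.788 in crypt against 3.14% ± 0.398 in colon, and colon regions at 88.1% ± 2.79 in colon against 46.5% ± 0.967 in crypt (SD, n = 3 each). The 2 duodenal regions on chromosomes 8 and 1 named for villus led the crypt direction too, and the chromosome 16 region led the colon direction, with no peak in crypt even in full lists. When a peak must cover 50% of the region, the chromosome 8 and 16 regions separated crypt and colon by 1 library instead of 3. There were 2616 regions exclusive to adult crypt and 3134 exclusive to adult colon, 5750 in all, against at most 210 in the other divisions and 8975 without adult colon library 1.

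The juvenile comparison asked whether the regional difference was present before weaning. The authors' deposited lists hold 5809 regions higher in juvenile duodenum and 5944 higher in juvenile colon. Duodenal regions had a peak at 66.5% ± 2.77 in duodenum and 3.59% ± 0.384 in colon, while colonic regions had a peak at 83.4% ± 0.722 in colon and 32.6% ± 1.38 in duodenum (SD, n = 3 each). Chromosome 3 at 16815419 to 16816360 had a peak in all 15 duodenum libraries and no colon library. Chromosome 12 at 78338885 to 78340549 had a peak in all 3 juvenile colon libraries and no juvenile duodenum library, although 12 duodenum libraries of later age had one. The chromosome 12 difference was 1 library when a peak must cover 50% of the region. There were 3654 regions exclusive to juvenile duodenum and 2090 to juvenile colon, 5744 in all, against at most 105 in the other divisions.

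In geriatric mice the lists were shorter. The authors' deposited lists hold 2092 regions higher in geriatric villus and 1681 higher in geriatric proximal colon, and for crypt 770 and 517 respectively. Villus regions had a peak at 49.8% ± 2.74 in villus (SD, n = 3) and at none in proximal colon, and crypt regions at 42.1% ± 4.63 in crypt (SD, n = 3) and 0.130% in each proximal colon library. Proximal colon regions had a peak at 46.0% ± 0.379 in proximal colon (SD, n = 2) against 1.15% ± 0.363 in villus (SD, n = 3), and at 65.7% ± 8.34 (SD, n = 2) against 5.22% ± 0.843 in crypt (SD, n = 3). The low crypt share depends on the cut to 11355 peaks. With full lists it was 36.2% ± 13.5 (SD, n = 3) against 78.1% in proximal colon. For villus the full lists gave 6.17% ± 1.37 (SD, n = 3) against 57.9%. The proximal colon regions set against villus were often open in crypt: with full lists, 70.0% ± 13.7 of them had a peak in geriatric crypt and 61.4% ± 8.18 in adult crypt, and 10.2% ± 2.95 in adult villus (SD, n = 3 each). The list was chosen for being lower in geriatric villus, so a low share in villus is partly built in. An example is chromosome 5 at 16777409 to 16778397, listed by the authors' deposited lists as higher both in proximal colon and in geriatric crypt than in geriatric villus. The duodenal region on chromosome 8 again headed the crypt direction, at 99392071 to 99393375. Exclusive regions numbered 3658 for villus and 2397 for crypt against proximal colon, compared with at most 1399 and 1117 in the other divisions of the 5 libraries. Both counts moved with the proximal colon libraries: without library 3 of that group they were 9203 and 6339, and without library 1 they were 6435 and 5152. The regions heading the proximal colon direction against crypt, on chromosome 3 at 122590493 and chromosome 1 at 157882694, had a peak in all 15 duodenum libraries with full lists. With a peak covering 50% of the region, the difference was 0 libraries for the regions on chromosomes 5 and 3 and 1 for that at 157882694, and with −log10 q of at least 5 it was 1 for chromosome 5.

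The direction of the regional difference was the same at all ages. Of 4054 regions in the authors' deposited lists for both juvenile duodenum against colon and adult villus against colon, 4026 (99.3%) pointed to the same tissue. The corresponding numbers were 3726 of 3801 for juvenile duodenum and adult crypt, 775 of 788 for juvenile duodenum and geriatric villus, 1525 of 1535 for adult and geriatric villus, and 648 of 650 for adult and geriatric crypt. The overlap in the same direction was 3.99 times the number given by the list lengths for juvenile duodenum with adult villus and 2.62 times for juvenile with adult colon. In Fisher's exact tests of direction the largest adjusted p of these 5 pairs was 2.55e-133. A set of 541 regions was listed as higher in duodenum at all 3 ages by the authors' deposited lists, and 125 as higher in colon. Of the duodenal set, 189 had a peak in all 15 duodenum libraries and in no colon library, such as chromosome 4 at 14949211 to 14950245. Of the colonic set, 6 had a peak in all 8 colon libraries and no duodenum library, the widest on chromosome 7 at 52898825 to 52899410. The chromosome 4 and 7 regions were chosen after their values were seen.

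Villus and crypt were compared within adult and within geriatric duodenum to describe differentiation along the crypt-villus axis. The authors' deposited lists hold 3118 regions higher in adult villus and 3520 higher in adult crypt, and 3929 and 2062 for geriatric villus and crypt. Adult villus regions had a peak at 82.1% ± 6.44 in villus and 14.9% ± 5.35 in crypt, and adult crypt regions at 75.3% ± 4.23 in crypt and 7.23% ± 1.31 in villus (SD, n = 3 each). The geriatric values were 88.9% ± 3.03 against 10.1% ± 2.62 and 78.1% ± 2.62 against 4.67% ± 1.36 (SD, n = 3 each). Villus regions near the top by separation were chromosome 10 at 82805908 to 82806962 in adults and chromosome 3 at 28361329 to 28362431 in geriatric mice. Leading crypt regions were chromosome X at 45637802 to 45638847 in adults and chromosome 4 at 75464846 to 75465954 in geriatric mice. Their separation rests on counting any overlap: with a peak covering 50% of the region it was 0 libraries on chromosomes 10 and X, 1 on chromosome 4 and still 3 on chromosome 3. The direction along the axis was the same at both ages: 2500 of the 2501 regions listed in both comparisons pointed to the same compartment, with 7.25 times the overlap given by list lengths for villus and 10.2 times for crypt. Adult crypt regions were also counted in geriatric libraries, which are not among the groups that list compares. They had a peak at 70.2% ± 4.77 in geriatric crypt and 11.1% ± 2.78 in geriatric villus (SD, n = 3 each, exact permutation p = 0.1). Whether peaks of geriatric libraries entered the set of regions the authors compared is not given in the sources used here. Exclusive regions numbered 5887 in adults and 6873 in geriatric mice, against at most 625 and 470 in the other divisions.

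**Figure D3:**
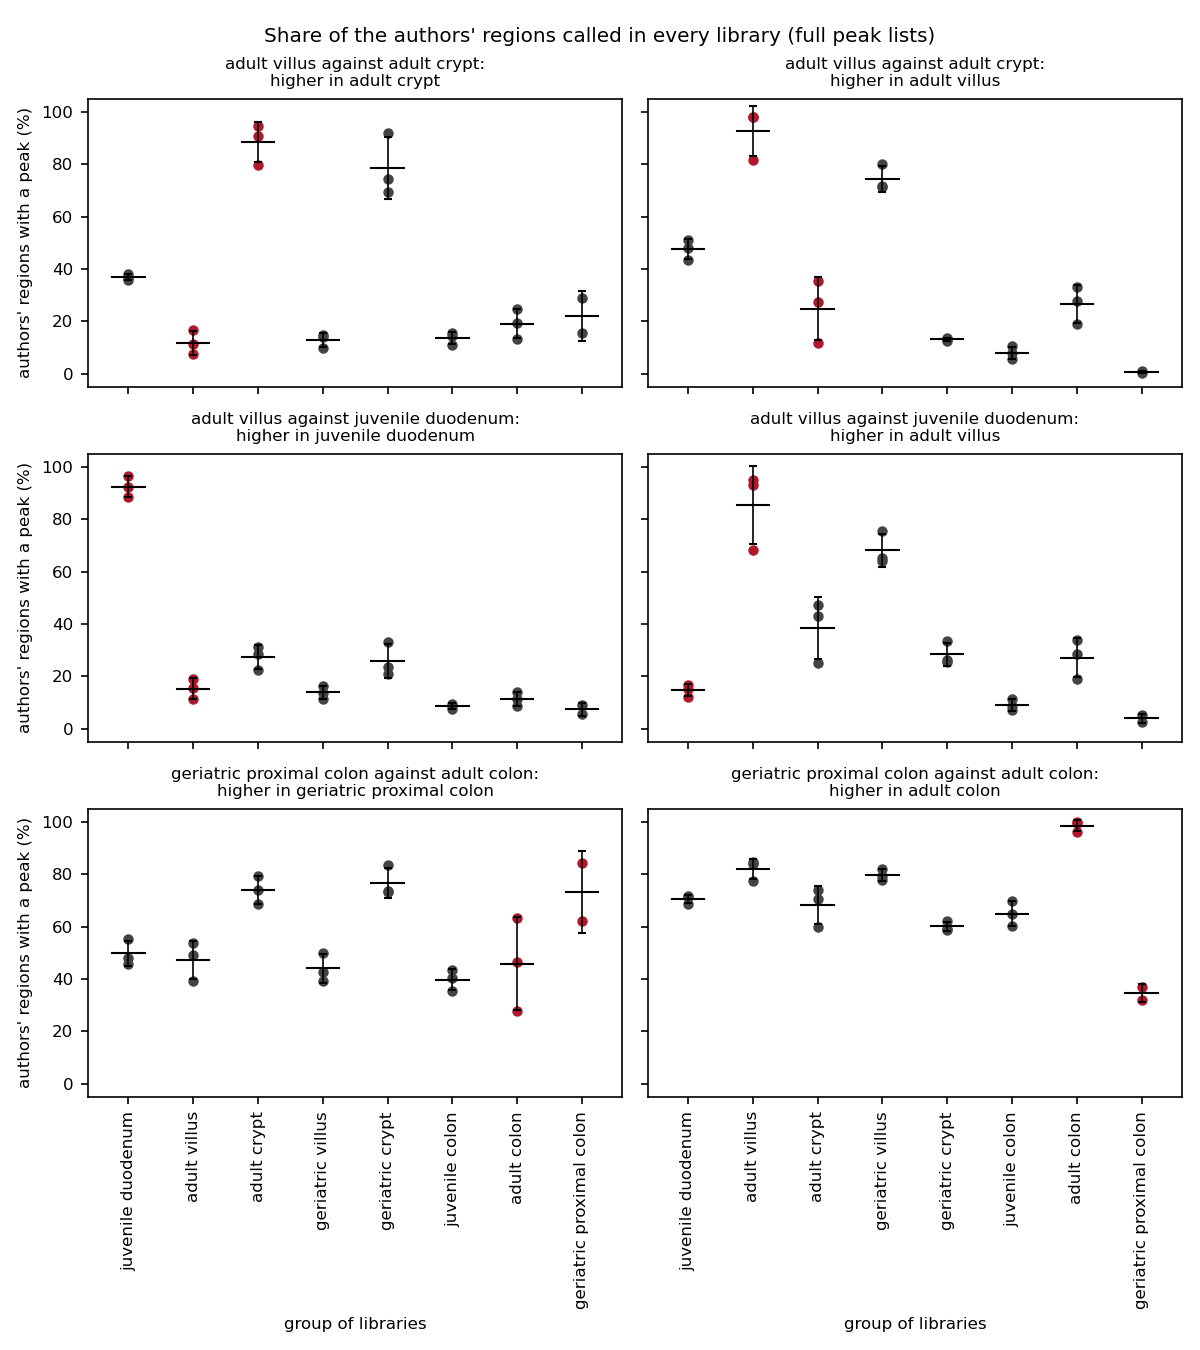
Share of the authors' regions with a peak (percent, full lists) in each library, for 6 of the authors' deposited lists; points are libraries, red for the groups compared and grey for the others, with the mean (line) and SD (bar) per group. Regions higher in adult crypt were called in 78.6% of cases in geriatric crypt, and those higher in geriatric proximal colon in 74.0% in adult crypt. Proximal colon libraries, whose lists are shorter, called 73.1% of the proximal colon regions, so the shares are not comparable between these groups. At 11355 peaks per library they were 60.9% in proximal colon and 26.5% in adult crypt.

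The largest change of the duodenum with age lay between juvenile and adult. Against adult villus, the authors' deposited lists hold 6783 regions higher in juvenile duodenum and 5922 higher in adult villus, and against geriatric villus 4850 and 4287. Juvenile regions had a peak at 86.9% ± 1.34 in juvenile duodenum and 13.8% ± 2.53 in adult villus, and adult regions at 80.5% ± 10.5 in adult villus and 11.5% ± 0.157 in juvenile duodenum (SD, n = 3 each). Chromosome 18 at 19690353 to 19691180 had a peak in the 3 juvenile duodenum libraries and in no other library of duodenum or colon, and headed both juvenile lists. Chromosome 11 at 109582500 to 109583838 had a peak in the 12 adult and geriatric duodenum libraries but in none of the juvenile ones and in no colon library. If a peak must cover 50% of the region, adult villus and juvenile duodenum differed by 1 library on chromosome 18 and by 0 on chromosome 11, and geriatric villus by 1 on both. With −log10 q of at least 5 the chromosome 11 difference for adult villus was 1 library. Exclusive regions numbered 8930 against adult villus and 7342 against geriatric villus, compared with at most 544 and 375 in the other divisions. The juvenile samples were whole epithelium, so age and crypt content are not separated in these lists. Among 1670 regions also listed for geriatric villus against geriatric crypt, 1618 paired juvenile duodenum with crypt and adult villus with villus (96.9%, Fisher's exact test, adjusted p = 2.62e-235). Of the juvenile regions, 21.5% ± 1.9 had a peak in geriatric crypt libraries and 12.8% ± 1.63 in geriatric villus (SD, n = 3 each, exact permutation p = 0.1). Both comparisons have villus on 1 side, and villus libraries did not part by age. The shared direction, and the low share of juvenile regions in geriatric villus, are therefore partly built in.

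The juvenile regions were also uneven by chromosome. Of the 6783 regions higher in juvenile duodenum than adult villus in the authors' deposited lists, 368 (5.43%) lay on chromosome X, against 2.93% of the catalogue (Fisher's exact test, odds ratio 2.16, adjusted p = 4.32e-31). Of the regions higher in adult villus, 42 (0.709%) did so. The labels used here do not give the sex of the animals, on which counts for chromosomes X and Y depend.

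In the colon, the authors' deposited lists hold 1987 regions higher in adult than juvenile colon and 1482 higher in juvenile colon. Adult regions had a peak at 95.5% ± 0.884 in adult colon and 52.8% ± 3.07 in juvenile colon, and juvenile regions at 70.8% ± 2.23 in juvenile and 16.8% ± 2.02 in adult colon (SD, n = 3 each). Chromosome 16 at 19452964 to 19453964 had a peak in the 3 adult colon libraries and in no other colon library, a difference of 1 library when a peak must cover 50% of the region. There were 1501 regions exclusive to adult colon and 483 to juvenile colon, 1984 in all, against at most 203 in the other divisions and 3117 without juvenile colon library 3. Against geriatric proximal colon, the authors' deposited lists hold 3033 regions higher in juvenile colon and 1092 higher in proximal colon. Proximal colon regions had a peak at 69.2% ± 2.78 in proximal colon (SD, n = 2) and 8.12% ± 0.140 in juvenile colon (SD, n = 3). Of these regions 39 lay on chromosome Y (Fisher's exact test, odds ratio 9.75, adjusted p = 4.71e-18). Among them 16 lay within 52 kb from position 2850499 and 7 within 15 kb from 2779662. Such neighbours are not independent, so the p-value does not show a change along the whole chromosome. Exclusive regions numbered 2155, against at most 596 in the other divisions, and 5972 or 5298 without proximal colon library 3 or 1.

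Regions listed for juvenile against adult in both duodenum and colon mostly pointed the same way. Juvenile duodenum was whole epithelium and the adult side was villus, so age and crypt content are not separated here. Of 431 regions listed both for adult villus against juvenile duodenum and for adult against juvenile colon in the authors' deposited lists, 376 (87.2%) changed in the same direction with age (Fisher's exact test, odds ratio 47.1, adjusted p = 1.74e-40). With geriatric villus in place of adult villus it was 257 of 295 (87.1%). Most of the shared regions rose with age: 300 were higher in both adult tissues, 2.60 times the number given by list lengths, and 76 were higher in both juvenile tissues, 1.94 times. The juvenile part depends on the background: over the whole catalogue it turned to 0.706 times (Fisher's exact test, p = 0.000785), and to 0.722 times with geriatric villus in place of adult villus. At equal list length, the adult villus regions had a peak at 35.2% ± 3.45 in adult villus and 1.33% ± 0.196 in juvenile duodenum, and at 17.6% ± 1.33 in adult and 7.75% ± 0.994 in juvenile colon (SD, n = 3 each). The change in duodenum is inflated in this comparison, because the regions were chosen on the duodenum libraries. The juvenile duodenum regions did not separate the colons, with 7.87% ± 0.376 in adult and 7.96% ± 0.320 in juvenile colon (SD, n = 3 each, exact permutation p = 1). Both colon lists differed in duodenum. Adult colon regions had a peak at 58.4% ± 2.16 in adult villus and 45.4% ± 0.191 in juvenile duodenum. Juvenile colon regions had one at 16.2% ± 1.63 in adult villus and 21.4% ± 1.63 in juvenile duodenum (SD, n = 3 each, exact permutation p = 0.1 for both). Against geriatric proximal colon in place of adult colon, only 143 of 284 regions (50.4%) pointed the same way as adult villus against juvenile duodenum (Fisher's exact test, odds ratio 0.545, adjusted p = 0.0410). Regions higher in adult colon than juvenile colon went with villus and those higher in juvenile colon with crypt in 289 of 317 regions also listed for adult villus against crypt (91.2%, Fisher's exact test, adjusted p = 7.12e-51).

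**Figure D4:**
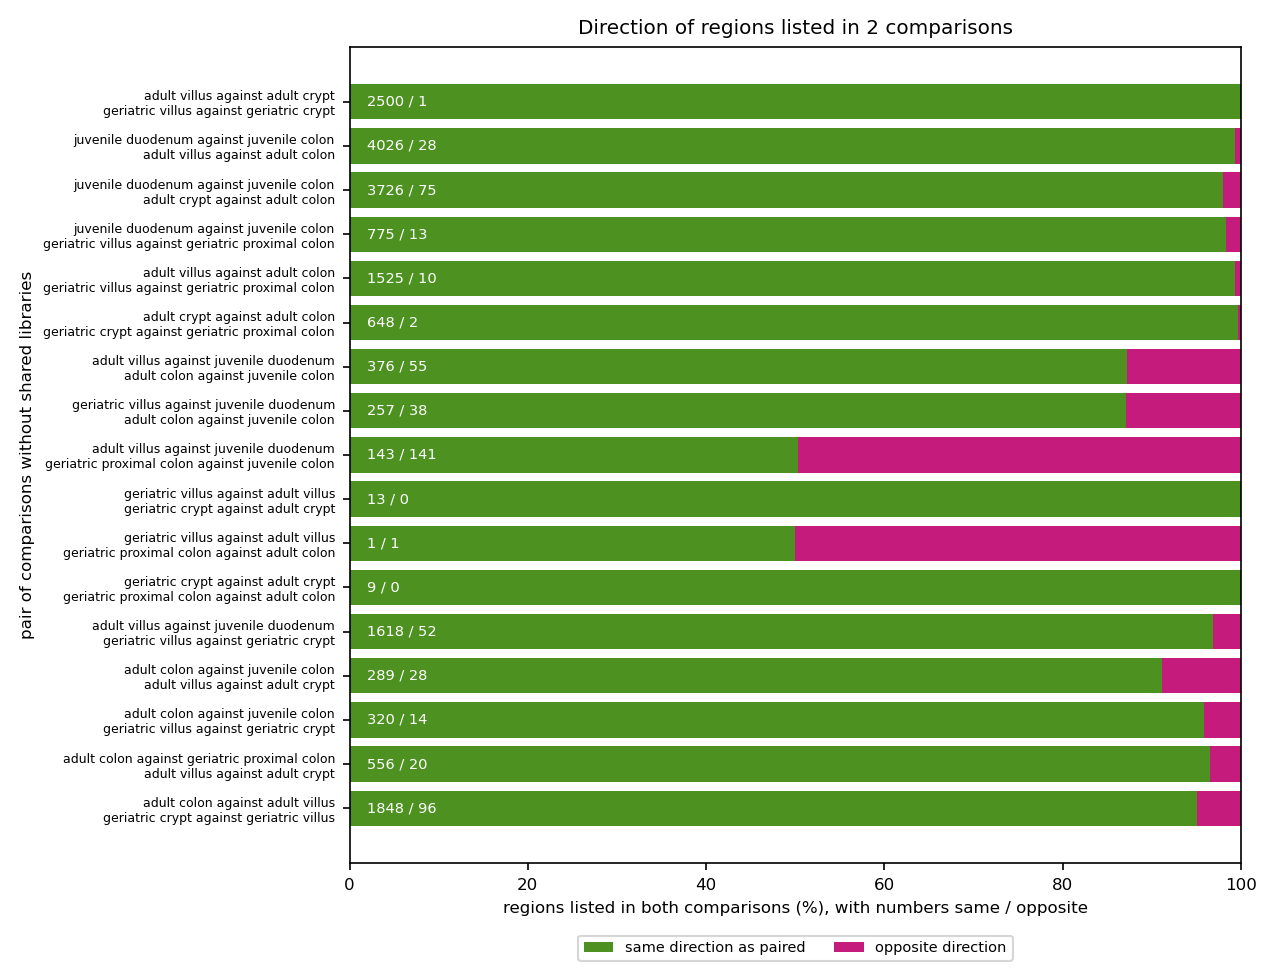
Share of regions (percent) that pointed the same way (green) or the opposite way (pink) among regions in the authors' deposited lists of 2 comparisons without common libraries, with their numbers. The same-way share was 99.96% for villus against crypt at the 2 ages and 50.4% for adult villus against juvenile duodenum paired with geriatric proximal colon against juvenile colon.

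Adult and geriatric duodenum differed little. The authors' deposited lists hold 64 regions higher in geriatric villus and 37 higher in adult villus, and 62 and 55 for geriatric and adult crypt. Geriatric villus regions had a peak at 36.5% ± 7.86 in geriatric and 4.17% ± 0.902 in adult villus, and adult villus regions at 41.4% ± 5.63 in adult and 0.901% ± 1.56 in geriatric villus (SD, n = 3 each). These means include 29 of the 64 and 7 of the 37 regions, which had no peak in either villus group even with full lists. For crypt the shares were 63.4% ± 8.88 against 10.2% ± 1.86 and 63.0% ± 7.35 against 2.42% ± 1.05 (SD, n = 3 each). At 35105 peaks, the adult crypt regions were also called in villus, at 66.1% ± 3.78 in adult and 48.5% ± 4.20 in geriatric villus. The geriatric crypt regions were called at 7.53% ± 2.46 in adult and 23.1% ± 4.93 in geriatric villus (SD, n = 3 each). Whether the crypt preparations of the 2 ages held the same share of villus cells was not tested. The villus libraries as a whole did not part by age. There were 575 exclusive regions, fewer than the 767 of another division of the same libraries, and the index was 0.592 within an age and 0.589 between ages, a difference in place 4 of the 10 divisions (exact permutation p = 0.4). The division with 767 set geriatric villus 1 and 2 and adult villus 1 against the rest. Those 3 libraries had read extensions of 210, 159 and 145 bp. Geriatric villus 3 and adult villus 2 and 3 had 116, 134 and 68 bp. Whether this technical difference hides a difference by age in villus was not tested. For crypt there were 680 exclusive regions against at most 595 in the other divisions, with an index of 0.586 within and 0.577 between ages (exact permutation p = 0.1). Leaving out 1 library raised these counts to between 1065 and 1502 for villus and between 1435 and 1917 for crypt, whichever library was left out. The difference in index turned to −0.00410 or −0.0126 for villus without adult villus library 2 or 3, and to −0.00390 for crypt with full lists.

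Villus and crypt shared more of their ageing regions than list lengths give, although most regions were listed for 1 compartment alone. Of the regions in the authors' deposited lists of both ageing comparisons, all 13 catalogue regions in the shared background changed the same way (Fisher's exact test, adjusted p = 0.000944). The overlap was 8 regions higher in adults and 5 higher in geriatric mice, against 0.0167 and 0.00910 given by list lengths. Without that background the authors' lists had 14 regions in common, 8 and 6. Villus and crypt libraries of an age may come from the same animals, so the 2 lists are not known to be independent. No geriatric duodenum library had a peak at any of the 8 adult-higher regions. Chromosome 4 at 145053564 to 145054306 and chromosome 8 at 89996306 to 89997052 had a peak in every juvenile and adult library of both tissues and in no geriatric library. Chromosome 1 at 142303240 to 142303541 and at 142312263 to 142312714 and chromosome 16 at 90091431 to 90091891 had one in all 9 juvenile and adult duodenum libraries and in no other library. Of the geriatric-higher regions, chromosome 1 at 27114992 to 27115523 had a peak in all 6 geriatric duodenum libraries and in no other library. Chromosome 1 at 24618400 to 24622997, which is 4598 bp wide, had a peak in all 23 libraries, so its listing rests on signal height. Whether the reads counted there belong to that place alone was not tested. That region was chosen after its values were seen.

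**Figure D5:**
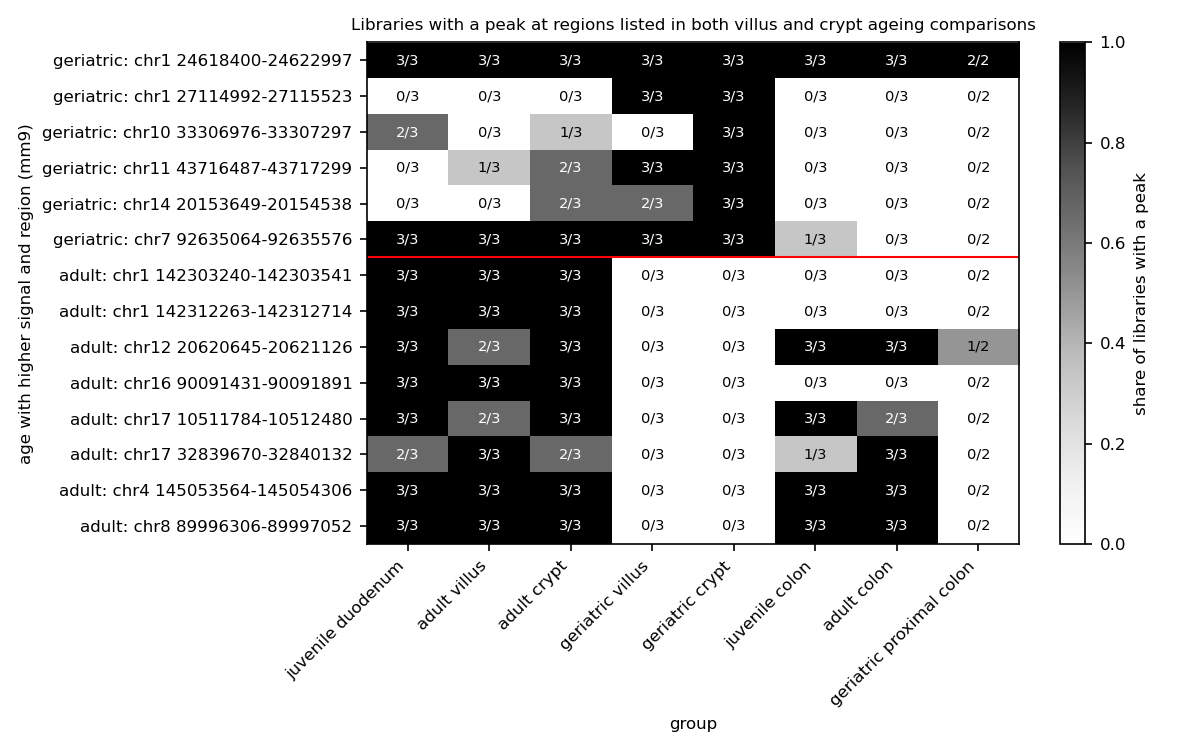
Number of libraries with a peak (full lists) over the libraries of each group, at the 14 regions in the authors' deposited lists of both the villus and the crypt ageing comparison; shading is the share of libraries. No geriatric duodenum library had a peak at the 8 regions higher in adults (under the red line).

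Some regions of the ageing lists had no peak in the groups compared. Of the 64 regions higher in geriatric villus in the authors' deposited lists, 29 had no peak in any geriatric or adult villus library with full lists, and all 29 had a peak in at least 2 juvenile duodenum libraries. Of the 37 regions higher in adult villus in the authors' deposited lists, 7 had no peak in either villus group, and these 7 had a peak in at least 2 juvenile duodenum libraries too. The crypt lists held 0 such regions. How the authors collected the regions they compared is not given in the sources used here, so peaks of juvenile duodenum in the villus lists do not show a return to a juvenile state. With no peak in any juvenile or adult library there were 13 of the 64 regions higher in geriatric villus and 32 of the 62 higher in geriatric crypt.

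Geriatric proximal colon differed from adult colon far more than geriatric from adult duodenum. The authors' deposited lists hold 1996 regions higher in geriatric proximal colon and 1744 higher in adult colon, although only the geriatric labels name a part of the colon, so age and part of the colon are not separated here. Proximal colon regions had a peak at 60.9% ± 1.56 in proximal colon (SD, n = 2) and 6.93% ± 1.62 in adult colon (SD, n = 3), and adult colon regions at 83.6% ± 2.1 in adult colon (SD, n = 3) and 32.7% ± 0.851 in proximal colon (SD, n = 2). With full lists the proximal colon regions stood at 73.1% in proximal colon and 45.8% ± 17.6 in adult colon (SD, n = 3). Of them, 28.4% had no peak in any adult colon library. Adult colon regions then stood at 98.6% in adult colon and 34.5% ± 3.45 in proximal colon (SD, n = 2). The proximal colon regions were open in crypt more than in villus. At the 11355 peaks of that comparison, 26.5% ± 1.53 had a peak in adult crypt and 12.8% ± 2.66 in adult villus. The shares were 30.1% ± 1.30 in geriatric crypt and 14.4% ± 1.29 in geriatric villus (SD, n = 3 each). Longer lists of the duodenum libraries were used for the test, 35222 peaks for adult and 35105 for geriatric ones. There 66.4% ± 2.23 had a peak in adult crypt and 37.4% ± 1.49 in adult villus, and 69.9% ± 0.806 in geriatric crypt against 40.9% ± 3.34 in geriatric villus (SD, n = 3 each, exact permutation p = 0.1 for both). These longer-list shares are not comparable with the 60.9% in proximal colon. Of 576 regions also listed for adult villus against crypt, 556 (96.5%) paired proximal colon with crypt and adult colon with villus (Fisher's exact test, adjusted p = 4.33e-137). Chromosome 12 at 56592518 to 56593883 had a peak in all libraries but those of geriatric proximal colon. The regions that headed the proximal colon list, on chromosome 7 at 71069551 to 71070960 and chromosome 11 at 3001151 to 3002521, had a peak in all 8 colon libraries with full lists, so these differ in strength and not in presence. With a peak covering 50% of the region their difference was 0 libraries, and with −log10 q of at least 5 it was 1 for chromosome 11. The chromosome 11 region lies close to the start of the assembled chromosome, where peaks are less secure. The list holds 44 regions on chromosome Y (Fisher's exact test, odds ratio 7.62, adjusted p = 7.32e-19). Among them 14 lay within 52 kb from position 2850957 and 9 within 18 kb from 2779662, and such neighbours are not independent. There were 1183 regions exclusive to proximal colon and 2205 to adult colon, 3388 in all, against at most 746 in the other divisions and 8175 or 6711 without proximal colon library 3 or 1.

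The ageing change of duodenum was compared with that from adult colon to geriatric proximal colon. For crypt, 9 of 9 shared regions changed the same way, 2 higher in geriatric and 7 higher in adult libraries (Fisher's exact test, adjusted p = 0.0315, or 0.2125 when regions must overlap by 50% of both). For villus 2 regions were shared and they split 1 and 1. Of the 20 tests of whether a list separated the ages or groups by a different amount in another tissue or age, none had a p under 0.06 or an adjusted p under 0.23. Each list was chosen on 1 of the 2 sides compared, so these tests do not show that the sizes were alike.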

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

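Of the regions in the authors' deposited lists of both comparisons, adult villus against juvenile duodenum and geriatric proximal colon against juvenile colon, 50.4% changed in the same direction (143 of 284). The value was picked out because the odds ratio of direction was under 1, at 0.545 (Fisher's exact test, adjusted p = 0.0410). With adult colon in place of geriatric proximal colon the share was 87.2%. The 2 shares were not tested against each other, and they come from different regions. The regions pointing apart were 87 higher in adult villus and in juvenile colon and 54 higher in juvenile duodenum and in geriatric proximal colon. Those pointing together were 122 higher in both juvenile tissues and 21 higher in adult villus and geriatric proximal colon.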

How the results depend on the processing

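Each of the 8 groups had at most 3 libraries, the proximal colon lists were short, and peaks give no value where none was called. Gene list, promoter, location and motif alternatives were not run, because no mm9 annotation or sequence was used here. The planned 50% rule for catalogue regions changed nothing by construction, since every peak lies within its merged region, and was replaced by an added rule that a peak must cover 50% of the region. Shares of the authors' regions kept their direction in every alternative, and exclusive counts on autosomes stayed within 1.5 times. Admitting regions called in 1 library could not change an exclusive count, since such a region has a peak in every library of its group. In the replicate block all 14 exclusive counts stayed within 1.5 times. With 3 against 3 libraries the paired rule is the same as the unpaired one, so those counts could not change. The exact sign-flip test of the shares cannot go below p = 0.25. Every library matched its own replicate number best in 1 of 14 comparisons, which does not settle whether libraries of equal number share animals.

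With full lists, which are longer, exclusive regions rose to 10097 for adult villus and colon, 9233 for adult crypt and colon, 16471 for juvenile duodenum and colon, 13043 for geriatric villus and proximal colon, 12092 for geriatric crypt and proximal colon, 883 for geriatric and adult villus and 6704 for proximal and adult colon. With −log10 q of at least 5, which shortens the lists, they were 1690 for geriatric villus and proximal colon, 1303 for geriatric crypt and proximal colon, 3682 for adult villus and crypt, 4495 for adult villus and juvenile duodenum, 1202 for proximal and juvenile colon and 1849 for proximal and adult colon. With a peak covering 50% of the region they were 3649 for adult villus and colon, 2341 for geriatric villus and proximal colon, 1568 for geriatric crypt and proximal colon, 2620 for adult villus and crypt, 4428 for geriatric villus and crypt, 5182 for adult villus and juvenile duodenum and 253 for geriatric and adult villus.

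Leaving out 1 library leaves fewer to satisfy. Exclusive regions then ranged from 6838 (without adult colon 3) to 9289 (without adult colon 1) for adult villus and colon, and from 6428 (without adult colon 3) to 8975 (without adult colon 1) for adult crypt and colon. Against proximal colon the range was 4432 (without geriatric villus 2) to 9203 (without proximal colon 3) for geriatric villus and 2998 (without geriatric crypt 1) to 6339 (without proximal colon 3) for geriatric crypt. It was 2317 (without adult colon 3) to 3117 (without juvenile colon 3) for adult and juvenile colon, 2642 (without juvenile colon 1) to 5972 (without proximal colon 3) for proximal and juvenile colon, and 3682 (without adult colon 3) to 8175 (without proximal colon 3) for proximal and adult colon. For ageing it was 1065 (without adult villus 2) to 1502 (without geriatric villus 3) in villus and 1435 (without adult crypt 1) to 1917 (without adult crypt 2) in crypt.

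The difference of the Jaccard index within and between ages turned to −0.00390 in crypt with full lists. In villus it ranged from −0.0126 (without adult villus 3) to 0.0214 (without geriatric villus 2), and the cause was not tested. With the whole catalogue as background the overlap over expected fell below 1 for juvenile duodenum and juvenile colon, at 0.706 in the adult comparisons and 0.722 with geriatric villus. Against proximal colon it was 0.480 for adult villus with proximal colon, 0.803 for juvenile duodenum with proximal colon and 0.592 for juvenile duodenum with juvenile colon. For the ageing regions of geriatric villus it was 0.675 with proximal colon and 0.766 with adult colon. The cause was not tested. With a reciprocal overlap of 50%, ageing crypt and colon regions still changed the same way in 100 percent, at an adjusted p of 0.2125. Of 56 leading regions, 2 per direction, the difference in libraries moved for 47 when a peak must cover 50% of the region, for 10 with −log10 q of at least 5 and for 18 with full lists, besides the 5 changes to −1 given below. The leading regions are the widest by the naming rule, and the cause was not tested. With full lists the named regions on chromosome 3 at 122590493 and chromosome 1 at 157882694 (proximal colon against geriatric crypt), chromosome 7 at 71069551 (against juvenile and adult colon) and chromosome 11 at 3001151 (against adult colon) had a peak in every library of both groups, so the difference of −1 library each follows from 2 against 3 libraries and is no change of direction.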

Other observations

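The tests of the 3 patterns, and what each split count would show, were written down after the results had been seen. Regions of the authors' deposited lists also lay in clusters, which were looked for after the lists had been examined, joining neighbours at most 20 kb apart. On chromosome 9, 9 regions higher in adult villus than adult colon stood between 46009013 and 46052581, where 9 catalogue regions lay, and 8 of the geriatric villus against crypt regions lay at 46008978 to 46052650, among 11. On chromosome 6, 8 regions higher in adult colon than villus stood between 52140746 and 52211060, among 10 of the catalogue. On chromosome 16, 13 regions higher in adult villus than juvenile duodenum stood between 34029803 and 34121814, among 15, and 10 higher in juvenile duodenum between 88570008 and 88652514, among 13. On chromosome 1, 4 regions higher in adult than geriatric villus stood between 142303240 and 142326094, among 4. No chance level was computed, and clusters can follow from the density of the catalogue alone. Clusters of proximal colon regions at chromosome 9 from 3000009 to 3036117 and 3038295 lie at the very start of the assembled chromosome, where repeats are common and peaks are less secure. Juvenile colon had such clusters too. Against adult colon, 9 of its regions lay at chromosome 9 from 3000010 to 3038303. Against juvenile duodenum, 16 lay at chromosome 11 from 3027031 to 3098323 and 9 at chromosome 17 from 3007276 to 3036492.

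Among the 10 comparisons of 3 with 3 libraries, the real exclusive count was the highest of 10 divisions in 9. It was 6087 (highest other 210) for adult villus and colon, 5750 (210) for adult crypt and colon, 5744 (105) for juvenile duodenum and colon, 5887 (625) for adult villus and crypt and 6873 (470) for geriatric villus and crypt. It was 8930 (544) for adult villus and juvenile duodenum, 7342 (375) for geriatric villus and juvenile duodenum, 1984 (203) for adult and juvenile colon and 680 (595) for geriatric and adult crypt. Each of these is 1 of 10. For geriatric and adult villus 4 of 10 divisions were as large, with 575 against a highest other of 767. In the 4 comparisons with geriatric proximal colon the real count was also the highest, at 3658 (1399) against geriatric villus, 2397 (1117) against geriatric crypt, 2155 (596) against juvenile colon and 3388 (746) against adult colon. A set of 10 divisions cannot give a share under 0.05.

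Of the regions higher in adult than in geriatric villus, 29 of 37 had no peak in any geriatric library, although 7 of the 37 had none in adult villus either, and of those higher in adult than in geriatric crypt, 18 of 55. The villus and crypt lists shared 8 regions, against 0.0167 given by list lengths, which argues against a purely random overlap (Fisher's exact test, adjusted p = 8.39e-21). That p-value counts regions as independent, although those at chromosome 1 from 142303240 and from 142312263 are neighbours. Villus and crypt of an age may come from the same animals, so the overlap does not separate age from differences between animals. Whether the change was limited to duodenum could not be settled. Of 16 such regions called in juvenile and adult colon, 4 (25%) had a peak in geriatric proximal colon, against 75.4% of 14180 other regions (Fisher's exact test p = 3.23e-05). These regions thus lacked a proximal colon peak more often than others. Only the geriatric labels name a part of the colon, so a missing peak may go with the part and not with age. A hypothesis is that the geriatric mice carry a strain or cohort variant, such as a deletion, at some of these places. A deletion would leave no peak, so it stays open, confounded with age, only for regions without a geriatric peak. Sequence reads of the same mice, or geriatric mice bred with the adults, would separate the 2.

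The regions higher in geriatric proximal colon than in adult colon went with crypt. A lower peak yield of the proximal colon libraries was left open: with full lists these regions were called 27.3 points more often in proximal colon than in adult colon, but they had been chosen for that difference. A hypothesis is that the proximal colon preparations held more crypt cells, for which 19% of 1980 regions (377) were also higher in adult crypt than villus. Age and preparation change together here and the part of the adult colon is not given, so this could not be separated, and adult proximal colon prepared in the same way would do so.

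Regions called in all 23 libraries were listed far more often as higher in adult colon than in adult villus, 2651 against 8 of 5226. Adult colon against adult crypt (2696 against 24) and juvenile colon against juvenile duodenum (1482 against 51) were alike. Geriatric proximal colon had few, 23 against 0 for geriatric villus and 30 against 0 for geriatric crypt. Within colon, adult was listed more often than juvenile (511 against 110) and than geriatric proximal colon (532 against 148). A hypothesis is a difference of scale between tissues, or between groups, that normalization may leave. Among regions that gained at least the median rank of the listed colon regions toward colon, 94.2% (1326 of 1407) were listed as higher in colon. Among those that gained as much rank toward villus, 0.220% (3 of 1364) were listed as higher in villus. That share restates how few of these regions were listed for villus, so it leaves the hypothesis open. The 36.3% of adult colon regions with no peak in any adult villus library lie outside this set and do not bear on it. A spike-in control or counts at shared regions would test it.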
